A study of Rattus norvegicus with 6 samples.

How the data were processed

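The series compared primary motor neuron cultures from embryonic day 13.5 rats, kept for 2 days in vitro and treated for 2 h with 1 microM camptothecin or with DMSO, the solvent. Camptothecin is a plant alkaloid that traps topoisomerase 1 on DNA. Each treatment had 3 arrays, and the labels call the 3 samples of a treatment biological replicates without saying how the cultures were separated, so p-values measure the spread between these samples. Per the labels' protocols, biotinylated cDNA was made from 1 microg of total RNA and hybridised to Affymetrix Rat Gene 1.0 ST arrays, which carry probes along the whole length of each transcript. The deposited values are log2 expression values, one per transcript cluster and array. The submitters' processing notes name RMA and oligo. Their versions, the probe annotation and the genome build are not given in the sources used here.

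The value table held 29214 transcript clusters on 6 arrays. The platform annotation gave 1 gene symbol to 15310 clusters, several to 323 and none to 13581, and names were used only for the first kind. Through their gene identifiers 15279 of the 15310 clusters matched the RefSeq gene table of the rat assembly GRCr8, and 31 did not. At gene level 14506 genes were tested, each by its cluster with the highest mean over the 6 arrays, and for the 527 genes with several clusters 0 had clusters called in opposite directions. Annotated genomic spans from GRCr8 were available for 99.79% of the genes. GRCr8 was used only for names, spans and neighbour relations, and no coordinates are given because the build behind the array is unknown.

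Array medians on the log2 scale ran from 6.31 to 6.33 with camptothecin and from 6.22 to 6.28 with DMSO, so they did not overlap. Pearson's r over all clusters was 0.992 to 0.995 between arrays of a treatment and 0.983 to 0.985 between treatments. Pairs of arrays of a treatment held exactly equal deposited values (a tolerance of 0, with up to 9 decimals) for 19 to 34 clusters, so none was a copy of another. The number of arrays limits the precision.

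The values were tested as deposited, without further normalization or a filter. The test was limma's lmFit and eBayes (limma 3.58.1, R 4.3.3), camptothecin minus DMSO, two-sided, with Benjamini-Hochberg adjustment over all 29214 clusters and a threshold of 0.05. Values are log2 changes with limma's standard error (SE), n = 3 per treatment. The word rose or fell is used only of genes past that threshold. Genes of 100 kb or more were tested as a set against all other genes with a span, and 24 gene lists against all other genes, with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and an exact permutation test of the array labels were run beside it. So was limma's fry, which asks whether the members of a set move one way on balance and does not compare them with other genes. The p-values of the lists were adjusted over the 24 lists.

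The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names the 12 largest rises and the 12 largest falls past the threshold whose 3 camptothecin values all lie on 1 side of the 3 DMSO values, leaving out symbols that start with LOC, RGD, Olr, Vom, Mir or Snor. It adds up to 4 past-threshold members of each list with the largest change, or the 1 member with the largest change where none passed. It also adds Top1, Top1mt, Top2a and Top2b, of which Top2b was not measured by a cluster with 1 symbol, and the 3 largest falls and 3 largest rises among genes of 300 kb or more. The lists cover p53 targets, immediate-early genes, very long neuronal genes, topoisomerases and repair, the BCL2 family and caspases, stress responses, heat shock, NF-kB targets, splicing factors, Notch and BMP response genes, histones, ribosomal proteins, the respiratory chain, axon guidance, ion channels and receptors, motor neuron disease genes, and markers of 8 kinds of cell or cell state.

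The alternatives were another quantile normalization, centring each array on its median, leaving out dim clusters, the replicate number as a block, eBayes with trend and robust, array weights, leaving out each array in turn, only clusters with 1 symbol, a threshold of 0.01, limma's treat against a 1.2-fold change, span thresholds of 50 kb and 200 kb, and the mean over the clusters of a gene. Centring each array on the ribosomal protein genes was added after seeing the data.

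The fit was tested on simulated data drawn from the real cluster means and residual spreads for camptothecin against DMSO, with 200 of 29214 clusters changed. Of those, 98% were recovered at a log2 change of 2, 74.5% at 1, and 0 at 0.5. Clusters that had not been changed made up 7.11% of the calls at a log2 change of 2 and 5.7% at 1. The real fit called 5248 clusters, which makes its adjusted threshold less strict than in the simulation. Changes down to 0.22 in size were called there, so the simulated recovery shares do not carry over to the real fit. A simulated shift of -0.2 in the 1631 long genes among 14474 genes was recovered as -0.20. Figures were drawn with matplotlib 3.10.9.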

Results

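Rat primary motor neuron cultures were profiled on 6 arrays after 2 h with 1 microM camptothecin or DMSO, 3 arrays for each treatment. Motor neurons are the spinal cord and brainstem neurons that drive muscle. The comparison asks which transcripts differ in level after short exposure to a topoisomerase 1 poison.

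Among the genes named here, Npas4 and Fos had the largest rises, and Marchf11 and Sipa1l2 the largest falls. Npas4, an activity-dependent neuronal transcription factor, rose 10.3-fold (log2 change 3.37, SE 0.14, n = 3 per treatment, adjusted p = 2.64e-05). Fos, a subunit of the AP-1 transcription factor, rose 5.02-fold (2.33, SE 0.08), and Hexim1, an inhibitor of the elongation kinase P-TEFb, rose 3.5-fold (1.81, SE 0.10). Marchf11, a membrane-associated ubiquitin ligase, changed by -2.32 on the log2 scale (SE 0.11, adjusted p = 3.8e-05), and Lgr5, a receptor for R-spondins, by -2.07 (SE 0.06). Top1, the target of the drug, fell by 0.64 on the log2 scale (SE 0.08, adjusted p = 0.00254).

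The other large rises were Tsx (1.90), Amy1 (1.75), Nr4a1 (1.72), Polg2 (1.63), Otor (1.55), Sertad1 (1.54), Tob1 (1.52), Gadd45b (1.47) and Egr1, which rose 2.82-fold. Nr4a1 and Egr1 encode transcription factors, Tob1 an antiproliferative protein and Polg2 the accessory subunit of the mitochondrial DNA polymerase. Amy1 lay below the median brightness of all clusters, with a mean of 4.02 in DMSO and 5.76 in camptothecin. The other large falls were Sipa1l2 (-2.24), Hivep2 (-1.95), Serpinb2 (-1.94), Ano6 (-1.93), Pdzrn4 (-1.87), Htr2a (-1.85), Ell2 (-1.83), Slc6a5 (-1.79), Fam107b (-1.76) and Nrp1 (-1.73). Htr2a encodes a serotonin receptor, Ell2 an elongation factor of RNA polymerase II, Slc6a5 the neuronal glycine transporter and Nrp1 a semaphorin receptor. Serpinb2 was also dim, at 6.06 in DMSO and 4.12 in camptothecin. Top1mt (-0.01, SE 0.09), which was dim with a mean of 6.15, and Top2a (-0.05, SE 0.07) did not pass the test. With arrays centred on the ribosomal protein genes Top2a passed (-0.29, adjusted p = 0.0325).

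**Figure D1:**
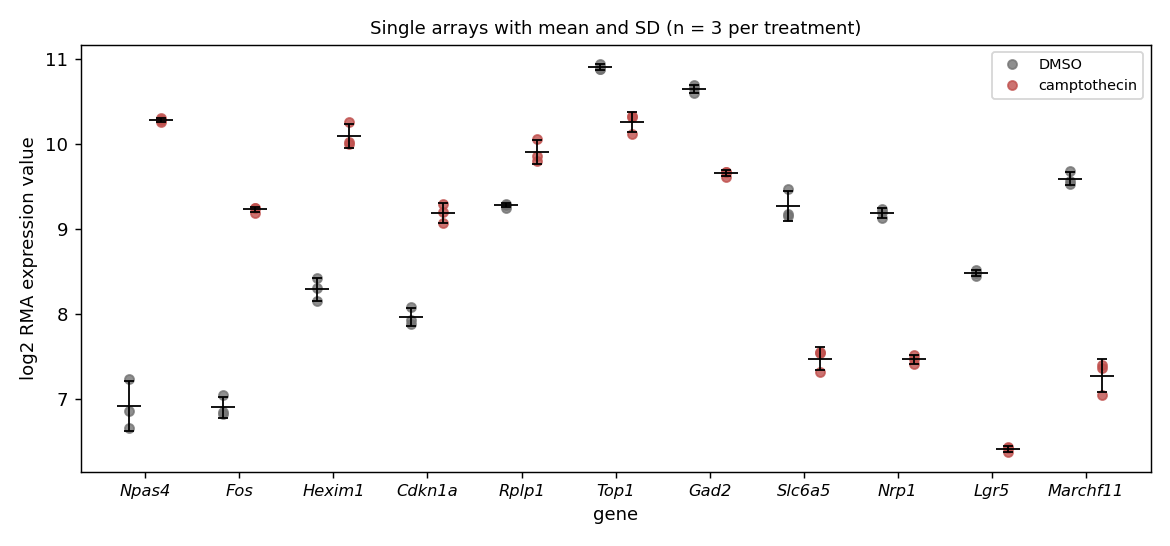
Log2 expression values of 11 named genes on each array, with DMSO in grey, camptothecin in red, and bars for the mean and SD of 3 arrays. Npas4 stands at 6.91 in DMSO and 10.28 in camptothecin, and Lgr5 at 8.48 and 6.41.

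Among the 14506 genes, 1643 rose and 1356 fell, and 11507 did not pass the test. Changes of 2-fold or more were found for 44 genes that rose and 152 that fell. Over all 29214 clusters, 2937 were higher and 2311 lower, of which 138 and 374 by 2-fold or more. Groups did not overlap for 37.5% of clusters, where chance gives 10%. The direction split depended on the scale: 56% of the called clusters were higher as deposited, 37.2% with each array centred on its median, and 8.82% with each array centred on the ribosomal protein genes. With 1 array left out the share was 41.9% to 54.7%, and lower calls outnumbered higher ones in 5 of the 6 such fits, all but that without camptothecin replicate 1. The ribosomal centring shifts the median change of all clusters by -0.24.

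Genes with a long genomic span were lower as a set, although most of them did not pass the test singly. Of the 1631 genes spanning 100 kb or more, 568 fell and 30 rose, so 34.8% fell against 6.13% of the other genes. Among genes of 300 kb or more, the largest falls were Hs3st5 (-1.47, SE 0.15), Fbxl7 (-1.47, SE 0.10) and Zfpm2 (-1.41, SE 0.07). Hs3st5 modifies heparan sulfate, Fbxl7 is an F-box protein and Zfpm2 a cofactor of GATA factors. The largest rises there were Grik1, a kainate receptor subunit (0.55, SE 0.08), Rpl29 (0.37, SE 0.07) and Tuba1c (0.37, SE 0.08). Rpl29 and Tuba1c owe their place to GRCr8 spans of 893 kb and 442 kb, while the median span of the ribosomal protein list was 3.26 kb.

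The median log2 change was 0.10 for genes under 10 kb, 0.11 from 10 to 30 kb, 0.00 from 30 to 100 kb, -0.12 from 100 to 300 kb and -0.19 at 300 kb or more. Of the 152 genes that fell by 2-fold or more, 107 (70.4%) spanned 100 kb or more, against 11.3% of all genes with a span. Of the 44 genes that rose by 2-fold or more, 42 (95.5%) spanned under 30 kb, against 64.4% of all genes with a span. The median span was 83.1 kb for genes that fell, 10.7 kb for genes that rose and 16.6 kb for the rest. Across genes, which are not independent replicates, Spearman's rho of span and log2 change was -0.31, and -0.34 to -0.24 for single camptothecin arrays. The median of the long genes was lower than that of the others by a difference of -0.21 (camera p = 3.93e-26 at the preset correlation, p = 0.00671 with an estimated correlation). The exact permutation p of the difference between long genes and genes under 30 kb was 0.1, the smallest that 3 arrays against 3 allow (two-sided).

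**Figure D2:**
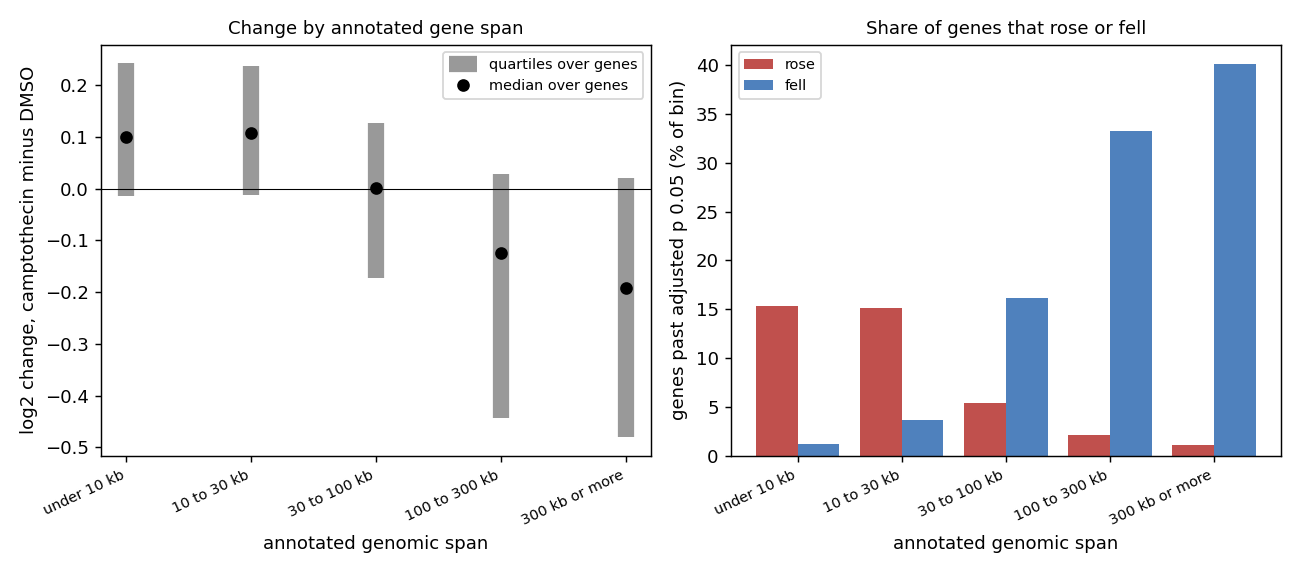
Left, log2 change of genes by annotated genomic span, with points for the median and bars for the quartiles over genes. Right, the percent of genes in each span bin that rose or fell. The median goes from 0.10 under 10 kb to -0.19 at 300 kb or more.

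Immediate-early genes and p53 targets were higher than other genes as lists in the main test. The adjusted p of the lists was 2.16e-11 and 9.97e-06, and adjusted p = 0.425 for both with an estimated correlation. Of 36 measured immediate-early genes, which respond to stimuli without new protein synthesis, 24 rose and 1 fell (28 and 1 adjusted over the list alone), led by Npas4, Fos, Nr4a1 and Egr1. Of 26 p53 targets, 14 rose and 1 fell (15 and 1 adjusted over the list alone). Tp53inp1 (1.43, SE 0.10), the kinase Plk3 (1.25, SE 0.10), the cyclin-dependent kinase inhibitor Cdkn1a (1.22, SE 0.09) and Phlda3 (1.16, SE 0.09) had the largest rises. Short-lived Notch and BMP response genes rose in 7 of 15 members and fell in 0 (10 and 0 adjusted over the list alone), with Hey2 (0.83), the dim Smad7 (0.48, mean 5.34 in DMSO), Hey1 (0.47) and Id2 (0.45), all transcription regulators or pathway inhibitors (list adjusted p = 0.000916, and adjusted p = 0.425 with an estimated correlation).

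Ribosomal protein and respiratory chain genes were higher by small amounts. The list adjusted p was 1.6e-08 and 3.62e-05, and adjusted p = 0.535 for both with an estimated correlation. Of 52 cytoplasmic ribosomal protein genes 27 rose and 0 fell (40 and 0 adjusted over the list alone), with Rplp1 (0.63), Rps15 (0.50), Rpl18 (0.49) and Rps19 (0.49). Of 38 respiratory chain genes 13 rose and 0 fell (18 and 0 adjusted over the list alone), with Cox4i1 (0.52), Atp5po (0.45), Ndufb8 (0.44) and Ndufa2 (0.42). The mean change of the respiratory chain list was 0.23 as deposited and -0.01 with arrays centred on the ribosomal protein genes. That of the ribosomal list went from 0.26 to 0.02, which centring on these same genes forces.

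Very long neuronal genes and axon guidance genes were lower than all other genes as lists, though not lower than random lists matched on span bin and brightness. The list adjusted p was 0.000343 and 0.0402, and adjusted p = 0.425 and 0.535 with an estimated correlation. Of 36 very long neuronal genes 14 fell and 1 rose (15 and 1 adjusted over the list alone), among them the netrin receptor Unc5c (-1.37, SE 0.07), the synaptic adhesion protein Il1rapl1 (-1.18, SE 0.11), the growth factor Nrg1 (-0.68) and the transcription factor Sox5 (-0.63). Of 36 axon guidance and outgrowth genes 11 fell and 3 rose (12 and 4 adjusted over the list alone), with Nrp1, Unc5c, the semaphorin receptor subunit Plxna2 (-1.09) and the receptor kinase Met (-0.86). The axon guidance list passed only in part of the alternatives, and its median (0.02) and mean (-0.18) differ in sign. Over the 24 lists 7 passed at the preset correlation, and another split of the 6 arrays also gave 7.

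Ion channel and receptor genes went both ways, with 8 of 37 falling and 6 rising (10 and 7 adjusted over the list alone). Glra1, a glycine receptor subunit, changed by -1.45, the metabotropic glutamate receptor Grm8 by -0.96, the potassium channel Kcna1 by -0.85 and the NMDA receptor subunit Grin2a by -0.74. Among the rises was Grik1 (0.55). Against random lists matched on span and brightness this list lay high, at percentile 99.5 by its median and 99.4 by its mean. The list did not pass the main test (adjusted p = 0.16; 0.0293 with fry), and its median (0.02) and mean (-0.10) differ in sign.

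The stress lists held risers and a few fallers, and none passed as a list in the main test, which compares a list with other genes. With fry, which asks only whether the members moved one way, the integrated stress (adjusted p = 0.0114), BCL2 (0.0293), heat shock (0.0293) and NF-kB (0.00893) lists passed. Integrated and endoplasmic reticulum stress genes rose in 7 of 18 members and fell in 1 (the same counts adjusted over the list alone; list adjusted p = 0.0514), with the chaperone Dnajb9 (1.01), Atf3 (0.84), Ppp1r15a (0.84) and Ddit4 (0.64). This list lay near the threshold and passed in 8 of 15 alternatives of the main test (adjusted p from 0.00757 to 0.548). In the BCL2 family and caspases 5 of 24 rose and 2 fell (8 and 2 adjusted over the list alone; list adjusted p = 0.16). The proapoptotic Pmaip1 rose by 0.68 and Diablo by 0.38, and the antiapoptotic Mcl1 and Bcl2 both changed by -0.48. Among heat shock genes 3 of 13 rose and 1 fell, with Dnajb1 (0.94), Cryab (0.59), Hsph1 (0.29) and Hspa4l (-0.45), and the list adjusted p was 0.664. Among NF-kB targets 3 of 17 rose and 1 fell, with Nfkbia, the inhibitor of the pathway (0.89), Ptgs2 (0.68), Ccl2 (0.35) and the subunit gene Nfkb1 (-0.96), and the list adjusted p was 0.304. In those last 2 lists the counts adjusted over the list alone were equal. Of the 17 NF-kB targets 10 were dim. Nfkb1 spans 116 kb, in the same span bin as Bcl2.

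Splicing factors and kinases rose in 6 of 21 members and fell in 2 (8 and 3 adjusted over the list alone), with Clk2 (0.59), Luc7l3 (0.50), Snrnp70 (0.47) and Rbm39 (-0.44), and a list adjusted p of 0.462. Of 20 topoisomerase and repair genes, Top1 fell and the DNA ligase Lig3 rose by 0.30 (list adjusted p = 0.16; adjusted over the list alone 1 fell and 0 rose). Of 12 histone genes Hist1h4b rose by 0.41 and the dim H1f5 changed by -0.66 (3 rose and 1 fell adjusted over the list alone; list adjusted p = 0.443). Of 18 motor neuron disease genes 4 rose and 1 fell (5 and 1 adjusted over the list alone; list adjusted p = 0.304), with Ubqln2 (0.47), Dctn1 (0.47), Kif5a (0.37) and Nek1 (-0.44).

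Among cell type markers, those of spinal interneurons and sensory neurons, taken as 1 list, fell in 5 of 18 members and rose in 0, the same counts adjusted over the list alone. Besides Slc6a5 these were the GABA-synthesising enzymes Gad2 (-0.99, SE 0.06) and Gad1 (-0.57, SE 0.07), the glutamate transporter Slc17a6 (-0.80, SE 0.08) and the transcription factor Pax2 (-0.25, SE 0.07), the last named after its value was seen. That list did not pass the main test (adjusted p = 0.16; 0.0106 with fry), and its median (0.05) and mean (-0.18) differ in sign. Of 18 motor neuron markers 3 rose and 2 fell (the same counts adjusted over the list alone; list adjusted p = 0.394; median 0.03, mean -0.03). Neurofilament genes Nefh (0.59) and Nefm (0.42) were among the rises, and Gfra2 (-0.69) and Foxp1 (-0.34) were the falls. In DMSO, Gad2 averaged 10.65, Slc6a5 9.26, the cell cycle gene Pcna 10.56 and Nefm 10.57, where array medians ran from 6.22 to 6.28. Levels of different genes do not measure the shares of cell types. Because interneuron and cell cycle genes lay well above those medians, changes in these cultures cannot be assigned to motor neurons alone.

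The other cell type lists did not pass the main test either. Neural progenitor and astroglial markers had 1 fall in 15 members (Pax6, -0.58; list adjusted p = 0.969). Oligodendrocyte and Schwann cell markers had 1 fall in 9 (Mbp, -0.48; 0.304, and 0.0293 with fry), and fibroblast markers 1 in 13 (Fn1, -0.36; 0.969). Endothelial, blood and microglial markers had 0 calls in 16 members by limma over all genes and over the list alone, with the largest value for Hbb (0.27, adjusted p = 0.279; list 0.707). Skeletal muscle markers had 1 rise and 1 fall in 11 (Acta1, 0.32; Pax3, -0.67; 0.932). Most members of these 2 lists were dim, 12 of 16 and 9 of 11, beside 6 of 13 fibroblast and 7 of 18 motor neuron markers, so few calls there do not show the absence of a change. Of 22 cell cycle genes 4 rose and 0 fell, led by Ccne1 (0.60), Pcna (0.44), Rrm2 (0.35) and Mcm7 (0.31; list adjusted p = 0.664). Counts adjusted over the list alone were equal in these lists. The calls of Ccl2, Lig3, Smad7, Acta1, Mcm7, Rrm2, Hsph1 and Kif5a were lost in 7 to 9 of the alternatives, mostly with an array left out. With arrays centred on the ribosomal protein genes the mean change turned below 0 for the BCL2, heat shock, NF-kB, splicing, histone, disease, endothelial and cell cycle lists, and for the progenitor, fibroblast and muscle lists it did so under each of the 3 scalings tried. For those last 3 lists camera gave the direction lower while median and mean were above 0.

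**Figure D3:**
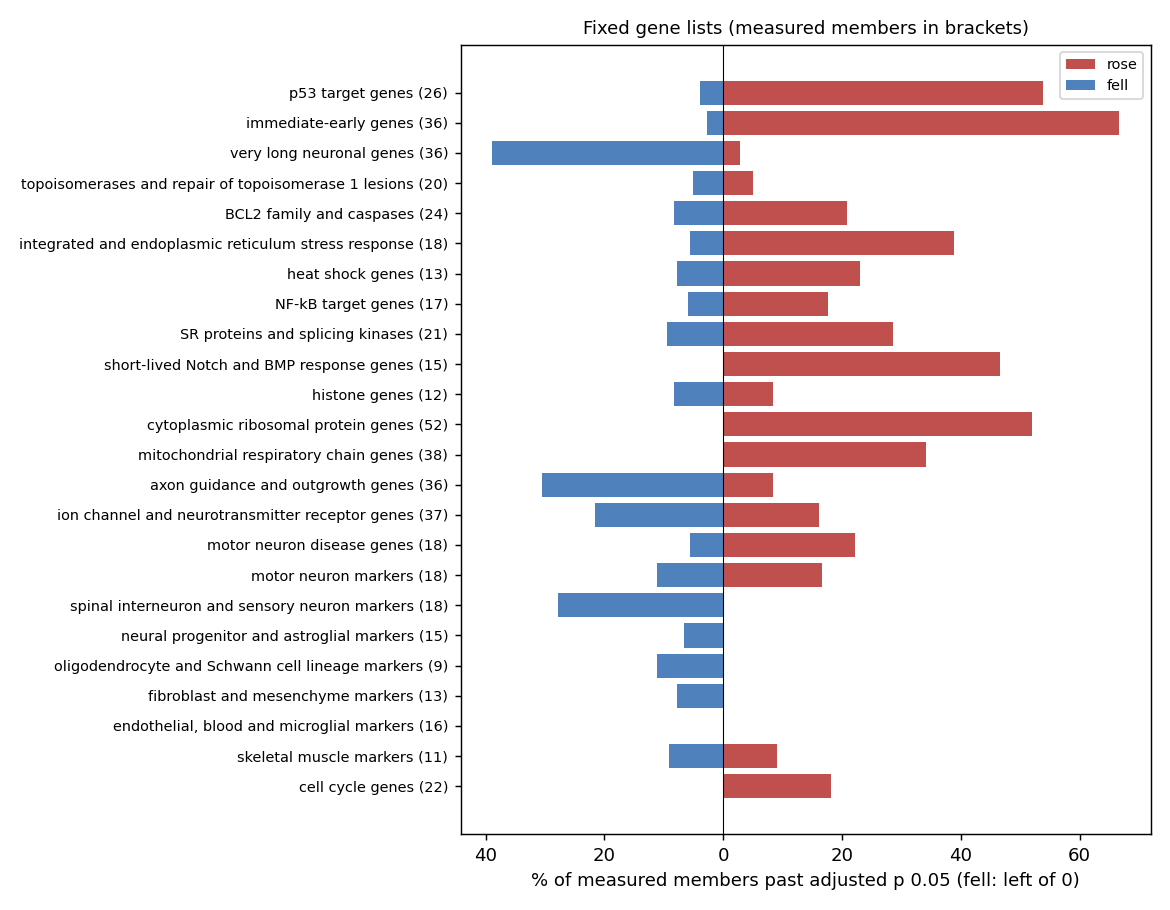
Percent of the measured members of each of 24 gene lists that rose (right of 0) or fell (left of 0) at an adjusted p under 0.05, with the number of measured members in brackets. Immediate-early genes had the largest share that rose (24 of 36), and very long neuronal genes the largest share that fell (14 of 36).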

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

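Centring each array on the ribosomal protein genes was chosen after seeing the data. Genes of 100 kb or more stayed lower past the threshold in every alternative run for them (p from 1.28e-26 to 0.00671). Either centring, the replicate block, and eBayes with trend and robust cannot change the size of the difference (-0.21), only its p-value. The counts below come from separate fits and are not shares of the main count. Higher clusters numbered 2937 in the main fit, 1627 with arrays centred on their median, 749 at a threshold of 0.01, 686 with ribosomal centring, and 1187 to 2327 with 1 array left out (1187 to 1913 without camptothecin replicate 2 or 3 or any DMSO array). The higher share of calls was 35.2% at a threshold of 0.01. Lower clusters numbered 2311 in the main fit, 7088 with ribosomal centring 1379 at 0.01, and 1581 to 2078 with 1 array left out. Clusters higher by 2-fold numbered 138 in the main fit, 73 without dim clusters, 63 with ribosomal centring and 45 with 1-symbol clusters only. Those lower by 2-fold numbered 374 in the main fit, 674 with ribosomal centring and 157 with 1-symbol clusters only. With treat against 1.2-fold, which does not ask for 2-fold, 313 clusters were higher and 908 lower. Fewer clusters are tested under the dim and 1-symbol settings, and the cause of the other changes was not tested. Over the 24 lists, 5 were higher in the main fit and 0 with an estimated correlation. The count was 6 with quantile normalization again, either centring, trend and robust, the mean over clusters, and without camptothecin replicate 1, DMSO replicate 2 or DMSO replicate 3, where the integrated and endoplasmic reticulum stress list also passed. Lower lists numbered 2 in the main fit, 1 with quantile normalization again, without dim clusters, with trend and robust, and without camptothecin replicate 2 (range 1 to 2 with 1 array left out), and 0 with an estimated correlation. Fry, which does not compare a list with other genes, gave 9 lists higher and 5 lower.

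With the replicate number as a block, 1677 clusters were higher and 1794 lower, so 48.3% of the calls were higher. The numbers do not pair the samples: deviations of same-numbered arrays correlated at -0.08, 0.02 and 0.08, and 2 of 6 arrays correlated best with their own number. Of 100 called genes among the 103 named, 0 changed sign, and 25 lost the call in some alternative: 22 with an array left out, 21 with ribosomal centring and 9 under the block. The others were Ndufb8, Nefm, Pax3, Fn1, H1f5, Rps19, Rps15, Rpl18, Rpl29, Ndufa2, Dctn1, Hist1h4b, Snrnp70, Diablo, Foxp1, Hey1 and Tuba1c, lost in 1 to 6 alternatives each, beside the 8 named in the report. Top2a alone gained a call, with ribosomal centring. Signal over background sets a limit for dim genes such as Amy1, Serpinb2 and Smad7.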

Other observations

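The tests of brightness, of single arrays, of scale and of matched gene lists were chosen after the medians they rest on had been seen. The tests of nested genes, of neighbouring genes and of other splits were written before their results were seen.

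Of 6034 genes below the median brightness of all clusters, 194 rose and 100 fell. As examples chosen after their values were seen, Ampd1, the muscle AMP deaminase, rose by 1.19 on the log2 scale (SE 0.11, mean 5.59) and Gnat2, the cone transducin, by 1.00 (SE 0.08, mean 5.95). Of the genes under 30 kb that lie inside a gene of 100 kb or more, 11 fell and 185 did not. The largest fall was that of F2rl2, a thrombin receptor gene of 5.04 kb (-1.46), whose host Iqgap2 was not measured by a cluster with 1 symbol. The hosts Cdc73 (-0.59), Gtf2f2 (-0.66) and Lrba (-0.74) fell with the genes inside them, and the hosts Dusp19 (0.29), Snd1 (0.20), Pdilt (-0.04) and Nipa1 (-0.02) did not pass the test.

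The lower level of long genes was set against brightness and single arrays. The median of genes of 100 kb or more lay -0.28 from the median of brightness-matched draws of genes under 30 kb, and below all 10000 draws (0.12 to 0.17). Each camptothecin array alone showed a difference of long minus short genes of -0.26 to -0.24, the smallest being -0.24. These values argue against brightness or 1 deviating array as the whole cause. The treatment itself stays open as the biological explanation, and no mechanism was tested. Among random lists matched on span and brightness, axon guidance genes lay at percentile 34.8 by their mean and 91 by their median, and very long neuronal genes at 81.2 and 95.7, which is consistent with the span of the members. The interneuron and sensory neuron markers lay at percentile 0.1 by their mean but 28.6 by their median, so the low mean rests on a few members. Span was matched in all these draws by span bin, the longest bin holding every gene of 300 kb or more. The very long neuronal list had a median span of 1107.6 kb, so within that bin its span was not matched.

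The higher level of ribosomal protein and respiratory chain genes as lists was set against scale. Their medians lay at percentiles 82.9 and 67.4 of random lists matched on span and brightness, which is consistent with a shift shared by bright short genes. With arrays centred on the ribosomal protein genes, the median change of genes under 30 kb was -0.13, but that centring fixes the value. Whether the listed genes became higher or the rest lower cannot be told apart on arrays without an external reference. A further comparison was added after that result was seen: a single factor per array would move all genes alike. The ribosomal protein genes exceeded all genes by 0.19 (0.16 to 0.24 on single arrays), which argues against such a factor as the whole cause. That difference follows from medians already seen and does not address a shift that varies with brightness. Genes under 10 kb had a median change of 0.10, and 0.22 at or above the median brightness. By median and by mean, 4 lists lay above the middle 95% of their matched lists: immediate-early genes (100 and 100), p53 targets (99.99 and 100), Notch and BMP response genes (97.7 and 99.2), and ion channel and receptor genes (99.5 and 99.4). The integrated stress list did so by its mean (97.9) but not by its median (63.2). All such draws take genes singly and so ignore correlation within a list. Its estimate was 0.13 for immediate-early genes, 0.16 for p53 targets, 0.11 for Notch and BMP genes and 0.03 for ion channel genes. The percentiles were not adjusted over the 24 lists.

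Dim genes that rose and short genes that fell may take signal from overlapping or adjacent transcription. Among dim genes under 30 kb, 30 of 143 that rose had an adjacent measured gene that rose, against 488 of 3918 others (odds ratio 1.87, 95% interval 1.19 to 2.85, Fisher's exact p = 0.00468), and the odds ratio was 0.96 among brighter genes. Of 218 genes under 30 kb that fell, 11 lay inside a gene of 100 kb or more, against 185 of 9110 others (odds ratio 2.56, 95% interval 1.24 to 4.79, Fisher's exact p = 0.00624). That test was not split by brightness. Under 10 kb, 46 of the 61 genes that fell lay at or above the median brightness, against 2123 of all 5049. From 10 to 30 kb it was 150 of 157, against 2709 of all 4279. A difference in brightness therefore cannot be told apart from nesting in that odds ratio. Genes are not independent, some hosts such as Rps10l6 have unusually long annotated spans, and the host's own fall did not settle the matter: 3 of 7 nested genes that fell had a measured host that fell, against 12 of 86 that did not fall (odds ratio 4.52, 95% interval 0.589 to 30.5, Fisher's exact p = 0.0805). Neighbours and hosts were found by position alone, without regard to strand or distance. These tests therefore cannot tell whether signal was taken from them. Both explanations stay open as hypotheses.

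The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split was reached or exceeded by 1 split, itself, for the 5248 changed clusters (highest other 0), for the 512 changed 2-fold (highest other 0) and for the long-gene difference of 0.21 in size (highest other 0.10). For the gene lists 2 of the 10 splits gave 7 lists past the threshold, the real one and 1 other.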
